A study of Mus musculus with 6 samples.

How the data were processed

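Chromatin accessibility was measured by ACC-seq in 6 libraries of R1 mouse embryonic stem cells, 2 each for Fresh, Fix and Fix_1,6-Hex cells. Cells were grown on mouse embryonic fibroblast feeder layers in medium with serum, LIF and 2i, and feeder cells were removed by replating, per the labels. Per the submitters' processing notes, the reads were processed with cutadapt 1.18, Bowtie2 2.3.3.1, Picard and SAMtools 1.6 on the mm10 assembly. How regions were called, merged over libraries and assigned to clusters is not given in the sources used here, and neither is the depth per library or the precision it gives.

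The deposited table gives, for each of 69689 accessible regions, the position and the cluster name assigned by the authors (cluster 1 to cluster 9). It has no column of signal, so the planned fits between groups, with a replicate term, without each replicate in turn and under other normalisations, had no values to run on. Positions start at 0 in the table and were counted from 1 here. Regions were 200 to 12664 bp wide and at least 1001 bp apart.

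Each region was placed by its midpoint against 21887 protein-coding genes of a gene table for the mm10 assembly that gives gene limits without strand, exons or sequence. Gene end means within 1 kb of either limit, gene body means inside a gene and not at a gene end, and intergenic means the rest. These classes replaced the planned transcription start sites, exons and introns. GC content, CpG, motif and repeat shares were planned and were not run, since no genome sequence was at hand. Selection by a score per region was not run because the table has no score.

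Shares of regions were compared between each cluster and all other regions by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family (27 tests of position, 162 of gene lists at gene ends, and all chromosomes by clusters) and an adjusted threshold of 0.05. Odds ratios carry 95% intervals by the Woolf method, with 0.5 added to each cell where a cell was 0, and shares of genes carry exact binomial 95% intervals. Widths and distances were compared by 100000 permutations of cluster labels. Pairs of adjacent regions within 10 kb were compared with 1000 permutations of labels within chromosomes. Distance to a listed gene ran from the midpoint of the region to the nearer end of the gene, so regions inside genes entered. A region counted once for each listed gene it lay near. Regions 1 to 50 kb from listed genes were compared with 10000 random lists of protein-coding genes of the same size, matched on decile of the number of distal regions. With these, the smallest possible permutation p is 1e-05, 0.001 (one-sided, pairs) and 0.0002. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

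The 18 gene lists, tests and most of the other settings were written before the data were examined, from general knowledge of these genes. Of 504 entries, 493 matched a protein-coding gene by symbol and 2 by synonym, and 9 did not match. Genes were named by a rule: for each cluster the 5 genes with most of its regions within 50 kb, for each list that passed the first 4 members in list order with a gene-end region, and for other lists the first 2. For regions around genes, the rule named the first 6 members with distal regions of the naive pluripotency and developmental lists. Some results at single genes are not reported here. The further genes of the naive list in cluster 6, Polr2a and the gene families given in the closing section were named after their values were seen.

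Other settings tried were windows of 500 bp and 2.5 kb, any overlap, all annotated genes, autosomes only, 1 region per 50 kb, regions of middle width, distal regions only, pairs within 2 kb and 50 kb, the nearest region only, and distances of 1 to 20 kb and 1 to 100 kb. Others, named in the closing section, were added after seeing the data. The methods were tested on simulated data with cluster labels permuted within chromosomes. This removes the resemblance of neighbouring regions and the link of clusters to gene ends. The draws therefore do not show the error rate for lists of adjacent genes. Gene-list tests at gene ends made 0 calls in 20 draws without a planted difference. A difference was planted by moving 40% of a list's gene-end regions into 1 cluster, on top of those already there. It was called in 15 of 20 draws. Distal lists made 0 calls, and a planted move of 30% of a list's distal regions was called in 6 of 20 draws. These draws used fewer random lists than the reported test, so a lone call could not pass and 0 calls was nearly given. Both distal counts depend on how many random lists each draw used, since that number sets the smallest possible p. They are therefore not taken as the error rate or the power of the reported distal test. A list without a distal call can still differ. Tests of position made 1 call in 20 draws and called a planted excess of 200 regions in 20 of 20.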

Results

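Open chromatin was profiled in R1 cells, a mouse embryonic stem cell line, by ACC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA. The 6 libraries fell into 3 groups of 2. Fresh cells were tagmented without fixation, Fix cells were held in 1% formaldehyde for 10 min, and Fix_1,6-Hex cells were kept in 10% (w/v) 1,6-hexanediol, an alcohol that dissolves many biomolecular condensates, for 30 s before fixation and again during it. Tagmentation lasted 30 min in all groups, at 37 °C for Fresh nuclei and at 55 °C for both fixed groups, so Fix and Fresh differed in temperature as well as in fixation. The study asked which features of accessibility respond when condensates are perturbed. The table analysed here covers the whole series and gives 69689 regions on mm10, each with the name of 1 of 9 clusters. It holds no value per library, so the contrasts of Fix with Fresh and of Fix_1,6-Hex with Fix had no measurement that could be tested, sequencing depth is unknown, and the accessibility pattern behind each cluster name is not given in the sources used here. The comparisons below are therefore between clusters of regions, and no direction between treatments is stated. Errors are the SD over 19 autosomes unless another is named. They describe spread along the genome, not between cultures.

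The clusters of accessible regions in these stem cells differed in how often they lay at gene ends and in how wide their regions were. Regions of clusters 2, 3 and 4 lay mostly at the ends of protein-coding genes, with 64.3% ± 7.37, 64.1% ± 3.49 and 62.7% ± 4.83 of regions there (SD, n = 19 autosomes). Cluster 8 followed with 45.9% ± 4.15. Clusters 6, 7 and 9 were mostly distal, with 9.10% ± 1.51, 5.42% ± 1.38 and 7.30% ± 1.55 at gene ends, and clusters 1 and 5 lay between, with 20.9% ± 2.04 and 16.7% ± 3.76. A region counted as at a gene end when its midpoint was within 1 kb of either annotated end of a protein-coding gene, because the gene table gives no strand and transcription start and end could not be separated. Of all regions, 18.9% were at a gene end, against a mean of 3.14% (range 2.93% to 3.51%) when the regions of each chromosome were rotated by a random offset in 100 draws.

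Against all other regions, the odds ratio for a gene end was 8.25 in cluster 2 (95% CI 7.43 to 9.16), 8.55 in cluster 3 (7.86 to 9.29), 7.99 in cluster 4 (7.34 to 8.70) and 4.36 in cluster 8 (4.13 to 4.60). It was 0.391 in cluster 6, 0.202 in cluster 7 and 0.262 in cluster 9. All 9 clusters differed from the remaining regions by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 27 tests. The smallest departures were those of cluster 1 (odds ratio 1.17, exact adjusted p = 3.25e-10) and cluster 5 (0.849, exact adjusted p = 0.000367). Neither passed with a window of 500 bp, and cluster 5 did not pass among regions of middle width. These p-values treat regions as independent and are too small, since neighbouring regions resemble each other. With 1 region per 50 kb, clusters 1 and 5 both passed (odds ratios 1.46 and 0.811). Together, clusters 2, 3 and 4 made up 9.36% of regions but 31.4% of gene-end regions, while clusters 7 and 9 made up 45.2% of regions and 15.5% of gene-end regions.

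Cluster sizes and widths varied with this position. Cluster 9 was the most numerous with 18283 regions (26.2% ± 1.80), followed by cluster 7 with 13205 (18.9% ± 1.87), cluster 1 with 13030 (18.7% ± 2.26), cluster 6 with 8821 (12.7% ± 2.03), cluster 8 with 6300 (9.04% ± 1.26), cluster 5 with 3528 (5.06% ± 1.08), cluster 3 with 2518 (3.61% ± 0.366), cluster 4 with 2420 (3.47% ± 0.444) and cluster 2 with 1584 (2.27% ± 0.348). The median width was 1366.5 bp in cluster 4, 1279 bp in cluster 3 and 1243.5 bp in cluster 2, against 345 bp in cluster 7 and 292 bp in cluster 9. The others lay between, at 496 bp in cluster 1, 817 bp in cluster 5, 583 bp in cluster 6 and 865 bp in cluster 8. The median distance from a region to the nearest gene end ran from 0.237 kb ± 0.200 in cluster 2 to 19.7 kb ± 3.88 in cluster 7. In each cluster, width and distance both differed from all other regions (permutation of cluster labels, two-sided, adjusted p = 1e-05, the smallest that 100000 permutations can give). Gene bodies, counted without gene ends, held 49.4% of cluster 7 and 49.2% of cluster 9 regions, and 18.6%, 20.5% and 21.3% of those of clusters 2, 3 and 4, of which more lie at gene ends.

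**Figure D1:**
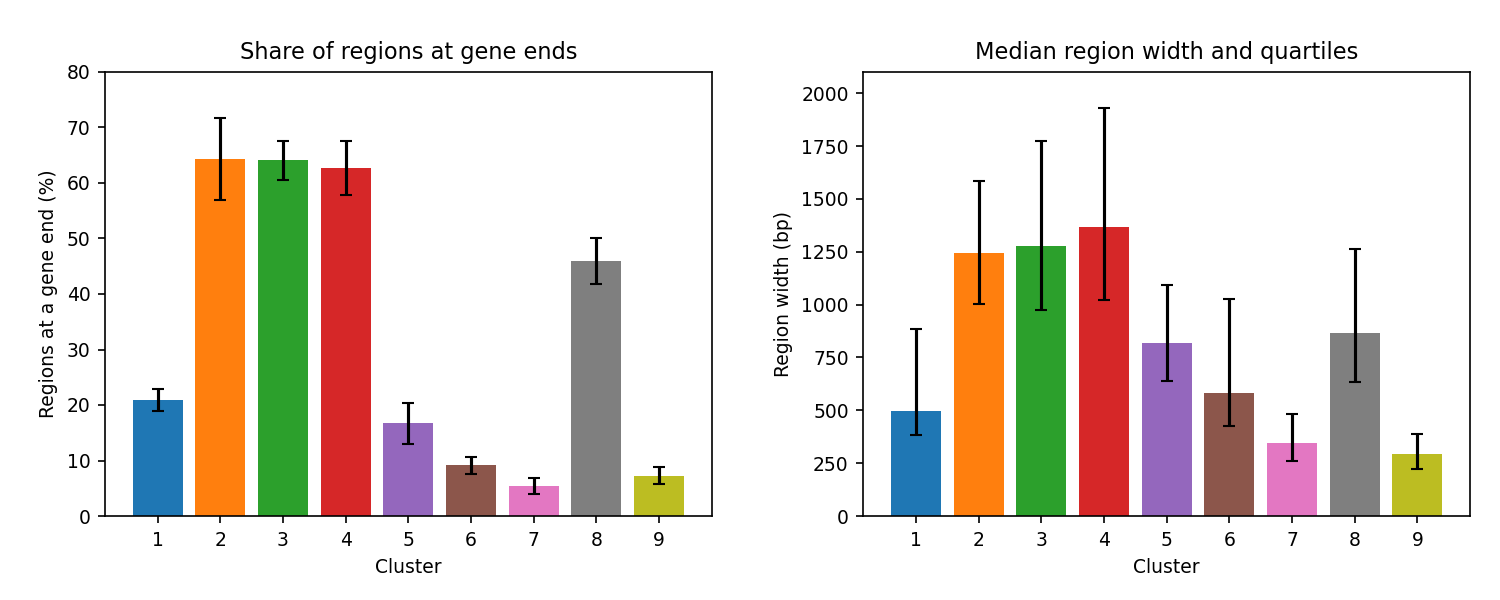
Left, share of the regions of each cluster whose midpoint lies within 1 kb of an end of a protein-coding gene (%), with the SD over 19 autosomes as error bars, and right, median region width (bp), with the lower and upper quartiles as bars. Clusters 2, 3 and 4 hold the widest regions and lie at gene ends in 64.3%, 64.1% and 62.7% of cases, whereas clusters 7 and 9 hold the narrowest, with 5.42% and 7.30% at gene ends.

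Some recognisable genes had many regions of 1 cluster within 50 kb. The gene with most cluster 6 regions within 50 kb was Klf5, a pluripotency factor of the Krüppel-like family (chromosome 14, 99298691 to 99313412), with 12 of its 19 regions. The 5 genes that ranked highest for cluster 3 all belonged to the histone gene cluster of chromosome 13, among them H1f3 (23555032 to 23555807, 6 of 17 regions) and H4c6 (23551286 to 23551668, 6 of 18). They lie side by side, so the same regions count for several of them, and because histone genes exist in near-identical copies these names are uncertain. Junb, an AP-1 subunit (chromosome 8, 84976909 to 84978748), was among the highest for cluster 8 with 9 of 17 regions, together with Ccnl2 (9 of 13) and Wdr24 (9 of 16). Cluster 9 regions were most numerous around Tbc1d22b (12 of 15 regions), Med13l, a Mediator kinase module subunit (12 of 16), and Sez6l (12 of 17). The leading genes were Gng7 (13 of 29) and Tab1 (12 of 18) for cluster 1, Rbbp9 (4 of 7) and Sec23b (4 of 8) for cluster 2, Pla2g10 (5 of 14) and Btn1a1 (5 of 18) for cluster 4, Lamc1 (6 of 24) and Rps23rg1 (5 of 14) for cluster 5, and Rbpms (11 of 21) and Dym (10 of 32) for cluster 7. These are ranks by the number of regions, in which long genes span more sequence, and they carry no test.

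Most housekeeping genes had an accessible region within 1 kb of an end, and genes of several differentiated tissues had it less often than genes at large. An accessible region lay at the ends of 31 of 31 proteasome subunit genes, 55 of 58 ribosomal protein genes, 36 of 38 oxidative phosphorylation genes, 25 of 27 genes of the condensate and transcription machinery and 23 of 25 immediate early and heat shock genes, against 60.9% of the 21887 protein-coding genes. Developmental transcription factors that Polycomb is known to occupy in embryonic stem cells were also covered more often, at 51 of 69 (73.9%, exact binomial 95% CI 61.9 to 83.7). Coverage was low for haematopoietic genes (2 of 20, the gene ends of Cd4 and Spi1) and genes of the 2-cell-like state (2 of 17, Zfp750 and Arg2). It was also low for muscle genes (6 of 19) and liver genes (7 of 20). Many genes of the 2-cell-like list are copies within a family, such as those named Zscan4 or Tdpoz. How well reads can be placed on such copies was not assessed, so their low coverage need not mean closed chromatin.

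These 10 of 18 lists differed from all other protein-coding genes (Fisher's exact test, two-sided, adjusted over 18 lists). The odds ratio was 11.8 for ribosomal proteins (exact adjusted p = 9.62e-08), 0.0713 for haematopoietic genes (exact adjusted p = 1.56e-05) and 0.0856 for the 2-cell-like list (exact adjusted p = 0.000151). These 3 lists passed with the other windows too, with odds ratios of 2.12 (39 of 58 genes), 0.0541 and 0.137 at 500 bp and 50.9, 0.233 and 0.0576 at 2.5 kb. Polycomb-bound developmental factors had an odds ratio of 1.83 (exact adjusted p = 0.0472). It was 9.56 with a window of 2.5 kb (exact adjusted p = 9.91e-07) and 4.65 with any overlap (exact adjusted p = 2.42e-05). It became 1.00 with a window of 500 bp. With that narrower window the immediate early and condensate lists did not pass either, and the muscle list did not with a window of 2.5 kb (odds ratio 0.742, exact adjusted p = 0.654) or with any overlap (0.380, exact adjusted p = 0.0742). Of the remaining lists, 22 of 31 naive pluripotency genes, 13 of 17 formative and primed pluripotency genes, 16 of 21 signalling targets, 14 of 19 imprinted genes, 16 of 20 neuronal genes, 10 of 17 primitive endoderm genes and 8 of 15 trophoblast genes had a gene-end region and none of these shares passed the test at 1 kb. With a window of 2.5 kb the naive pluripotency list passed (odds ratio 27.3, exact adjusted p = 6.35e-05), as did the signalling list (18.6, exact adjusted p = 0.00226), and with any overlap both passed as well (15.7 and 10.5). Fibroblast genes, the markers of the feeder layer on which the cells were grown, had a gene-end region in 20 of 30 cases (66.7%, exact binomial 95% CI 47.2 to 82.7), and this did not differ from other genes (exact adjusted p = 0.637).

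Genes of naive pluripotency stood apart by cluster 6. Of the 22 naive genes with a gene-end region, 8 (36.4%, exact binomial 95% CI 17.2 to 59.3) had a cluster 6 region there, against 6.65% of the 13299 other genes with a gene-end region. Among them were Nanog, a core pluripotency factor, the Krüppel-like factors Klf4 and Klf5, the germ and stem cell genes Dppa2 and Dppa4, Utf1 and Lefty1, a Nodal antagonist. The best known partners of Nanog were in other clusters, with Pou5f1 (which encodes OCT4) in cluster 4 and Sox2 in cluster 8, and Esrrb had gene-end regions of clusters 7 and 9. Developmental transcription factors stood apart by cluster 1, with 27 of 51 genes (52.9%, exact binomial 95% CI 38.5 to 67.1) against 21.5% of other genes, among them Hoxa5 of the HoxA cluster. Hoxa2, Hoxa13 and Hoxb1 had gene-end regions of cluster 9, as did 13 of the 51 genes of this list (25.5%, against 10.3% of other genes, odds ratio 2.97), which did not pass the adjustment (exact adjusted p = 0.0847).

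The odds ratio was 8.02 (3.35 to 19.2) for naive genes and cluster 6 (exact adjusted p = 0.00439) and 4.11 (2.37 to 7.14) for developmental factors and cluster 1 (exact adjusted p = 0.000143). They were the 2 calls among 162 tests of 18 lists and 9 clusters (Fisher's exact test, two-sided). With a window of 500 bp the naive call ended (odds ratio 5.63, exact adjusted p = 0.501), and cluster 7 had the larger odds ratio for naive genes (9.33, exact adjusted p = 0.126). With a window of 2.5 kb naive genes passed for cluster 7 as well (10 of 31 genes, odds ratio 4.08, exact adjusted p = 0.0313), and ribosomal protein genes passed for clusters 3, 4 and 6 (odds ratios 2.72, 2.64 and 4.00).

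The cluster 6 region of Nanog spanned 122706182 to 122710339 of chromosome 6 and reached into the gene (122707489 to 122714633). The cluster 4 region at Pou5f1 spanned 35502215 to 35510049 of chromosome 17 and covered 1 end of the gene (35506032 to 35510777). At Sox2 (chromosome 3, 34649995 to 34652461) the cluster 8 region spanned 34647779 to 34651360. Esrrb (chromosome 12, 86361117 to 86521628) had a cluster 9 region of 309 bp at 1 end and a cluster 7 region of 241 bp at the other. The region at Hoxa5 (chromosome 6, 52201754 to 52204587) spanned 52203436 to 52206074. Those at Hoxa2 and Hoxa13 were 200 bp and 2312 bp wide, and that at Hoxb1 (chromosome 11, 96365746 to 96368254) spanned 96365431 to 96366958. The gene table gives gene limits only, so exons, introns and UTRs are not named.

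In the other lists no cluster passed the adjustment. Ribosomal protein genes had cluster 3 regions in 16 of 55 genes and cluster 4 regions in 16 of 55 (exact adjusted p = 0.112 and 0.0847), with Rpl3 in cluster 4 and Rpl4 in both. Among proteasome genes, Psma1 and Psma2 were in cluster 4, and only 1 of 31 genes had a cluster 1 region (exact adjusted p = 0.116). Oxidative phosphorylation genes had cluster 1 regions in 2 of 36 genes (exact adjusted p = 0.146), 1 of them Ndufa1, and Ndufa2 was in cluster 3. Cluster 2 took 7 of 25 genes of the condensate and transcription machinery (exact adjusted p = 0.116), which include Med1 and Polr2a. Fos and Fosb, immediate early AP-1 genes, were both in cluster 8, a cluster found at 6 of the 23 genes of their list (26.1%), close to the 24.1% of other genes (exact adjusted p = 1). Formative and primed genes had cluster 1 regions in 7 of 13 cases (exact adjusted p = 0.135), with Fgf5 in cluster 1 and Dnmt3b in cluster 8. Stat3 was in cluster 3 and Lifr in cluster 8. Of imprinted genes, Mest was in cluster 9 and Plagl1 in cluster 2. Cluster 9 took 7 of 20 fibroblast genes (exact adjusted p = 0.0847), with Col1a2 in cluster 9 and Col1a1 in cluster 1. This association passed when only the region nearest to the gene end was counted (odds ratio 6.05, exact adjusted p = 0.0398). Neuronal genes had cluster 6 regions in 5 of 16 cases (exact adjusted p = 0.0847), with Syt1 in cluster 6 and Snap25 in cluster 8. Liver genes had cluster 7 regions in 3 of 7 cases (exact adjusted p = 0.112), among them Apoa1, with Apoa2 in cluster 3. Sox17 was in cluster 6 and Sox7 in cluster 9 among primitive endoderm genes, Eomes in cluster 8 and Tfap2a in cluster 6 among trophoblast genes, and Myod1 in cluster 9 and Ckm in cluster 8 among muscle genes.

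**Figure D2:**
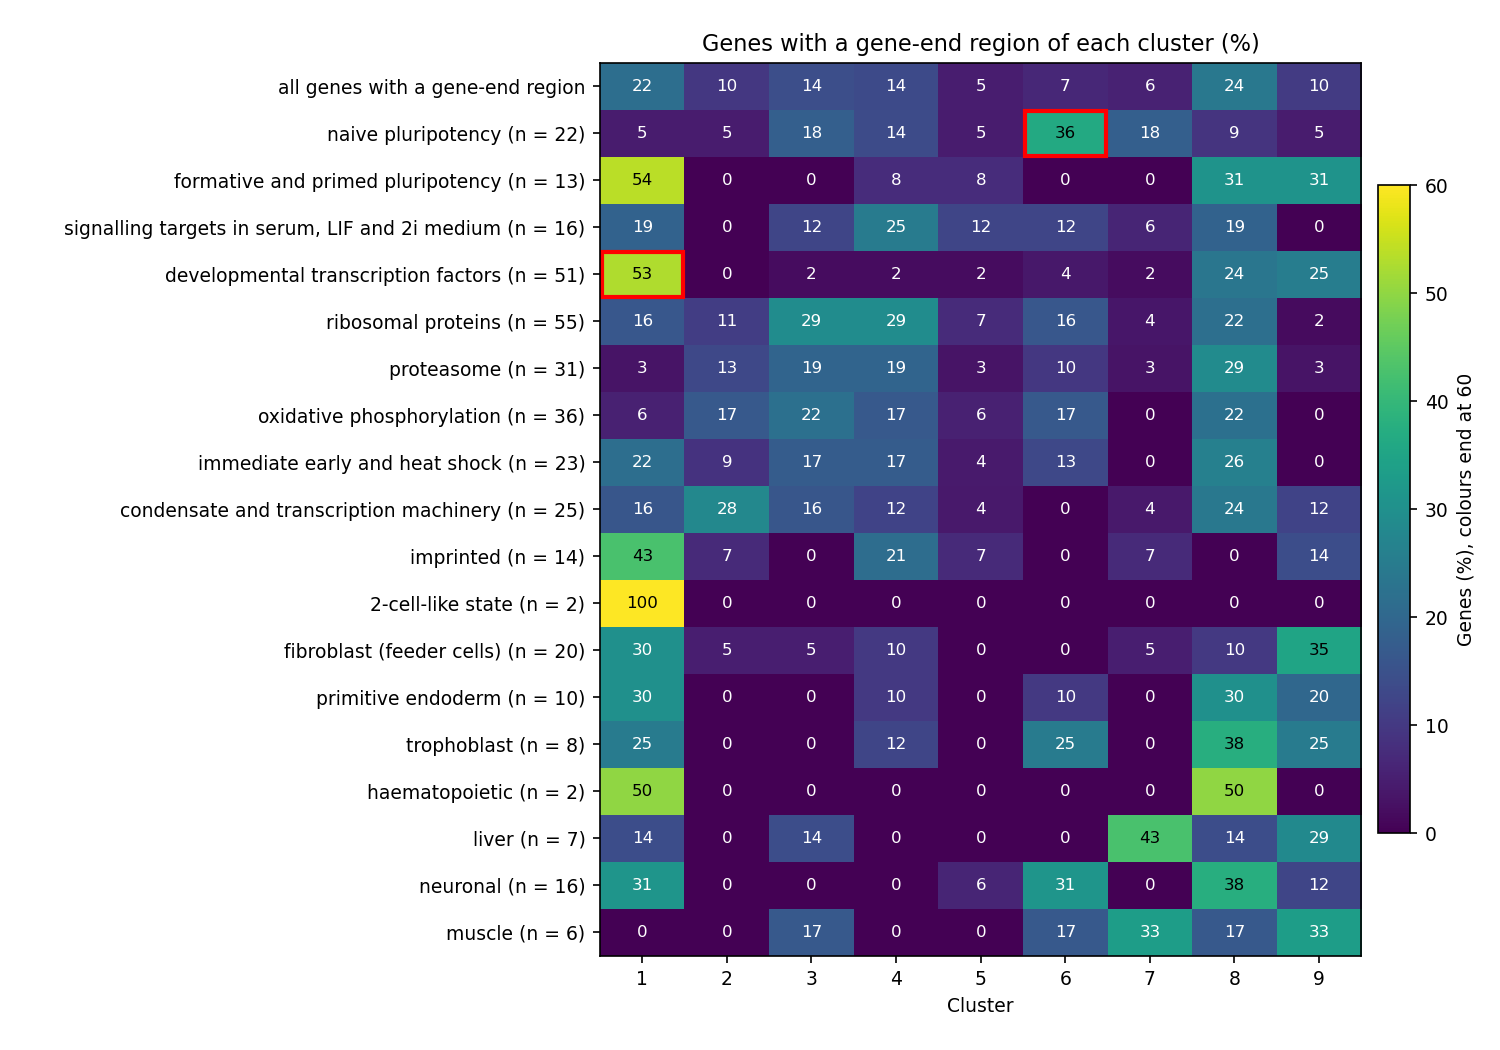
Share (%) of the genes of each list, among those with a gene-end region (n in brackets), that had a gene-end region of each cluster. The top row gives all genes, the colour scale ends at 60%, and red frames mark the 2 combinations that passed the adjusted threshold, naive pluripotency with cluster 6 (36.4%) and developmental transcription factors with cluster 1 (52.9%).

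The same pairing of lists and clusters was seen in the regions around these genes. Each region was counted once for every listed gene it lay 1 to 50 kb from, so neighbouring genes share regions. Distances ran to the nearer end of the gene, and regions inside genes entered. Of 359 such gene-region pairs of naive pluripotency genes, 21.2% belonged to cluster 6, against a mean of 10.4% in random gene lists. Cluster 8 held 5.57% of them, against 11.9%. For developmental transcription factors, 35.8% of 545 gene-region pairs belonged to cluster 1, against 21.9%. The 3 clusters typical of gene ends were scarce there. They held 0.183% (cluster 2), 1.28% (cluster 3) and 0.917% (cluster 4), against 2.68%, 4.34% and 4.27%. Nanog had 5 cluster 6 regions among 19, Esrrb had 4 among 13, and Pou5f1 and Klf2 had 2 each among 15 and 13. Sox2 had 1 of 9 and Klf4 1 of 4. The HoxA cluster, which patterns the body axis, had 27 distinct regions within 50 kb of Hoxa2, Hoxa5, Hoxa9 or Hoxa13. Of these, 10 belonged to cluster 1 and 8 to cluster 9, and none to cluster 2, 5 or 6. Around Hoxb1, 6 of 8 regions belonged to cluster 9.

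These 6 combinations passed against 10000 random lists of protein-coding genes matched on the number of distal regions. The permutation adjusted p was 0.0162 for naive genes with cluster 8 and 0.00648 for each of the other 5. The random lists were not matched on how close together their genes lie. All 6 also passed with 1 gene per 500 kb, an alternative added after seeing the data. In it, cluster 1 held 33.3% of 360 gene-region pairs for developmental factors (permutation adjusted p = 0.0108). At 1 to 20 kb only naive genes with cluster 6 and developmental factors with cluster 1 passed (both permutation adjusted p = 0.0324). Naive genes with cluster 8 and developmental factors with clusters 2, 3 and 4 did not (permutation adjusted p = 0.451, 0.0891, 0.213 and 0.0540). Another alternative added after seeing the data left out regions within 1 kb of the end of any protein-coding gene. Only developmental factors with cluster 1 then passed (34.4% of 453 gene-region pairs, permutation adjusted p = 0.0324). Naive genes with cluster 6 had a ratio of 1.65 (permutation adjusted p = 0.0756). No other list passed at 1 to 50 kb. At 1 to 100 kb, fibroblast genes passed for cluster 9, with 36.6% against 25.9% (ratio 1.41, permutation adjusted p = 0.0278). Developmental factors passed for cluster 9 at that distance too, with 30.3% of 905 gene-region pairs (ratio 1.21, permutation adjusted p = 0.0486). Passing for cluster 9 was therefore not particular to fibroblast genes.

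**Figure D3:**
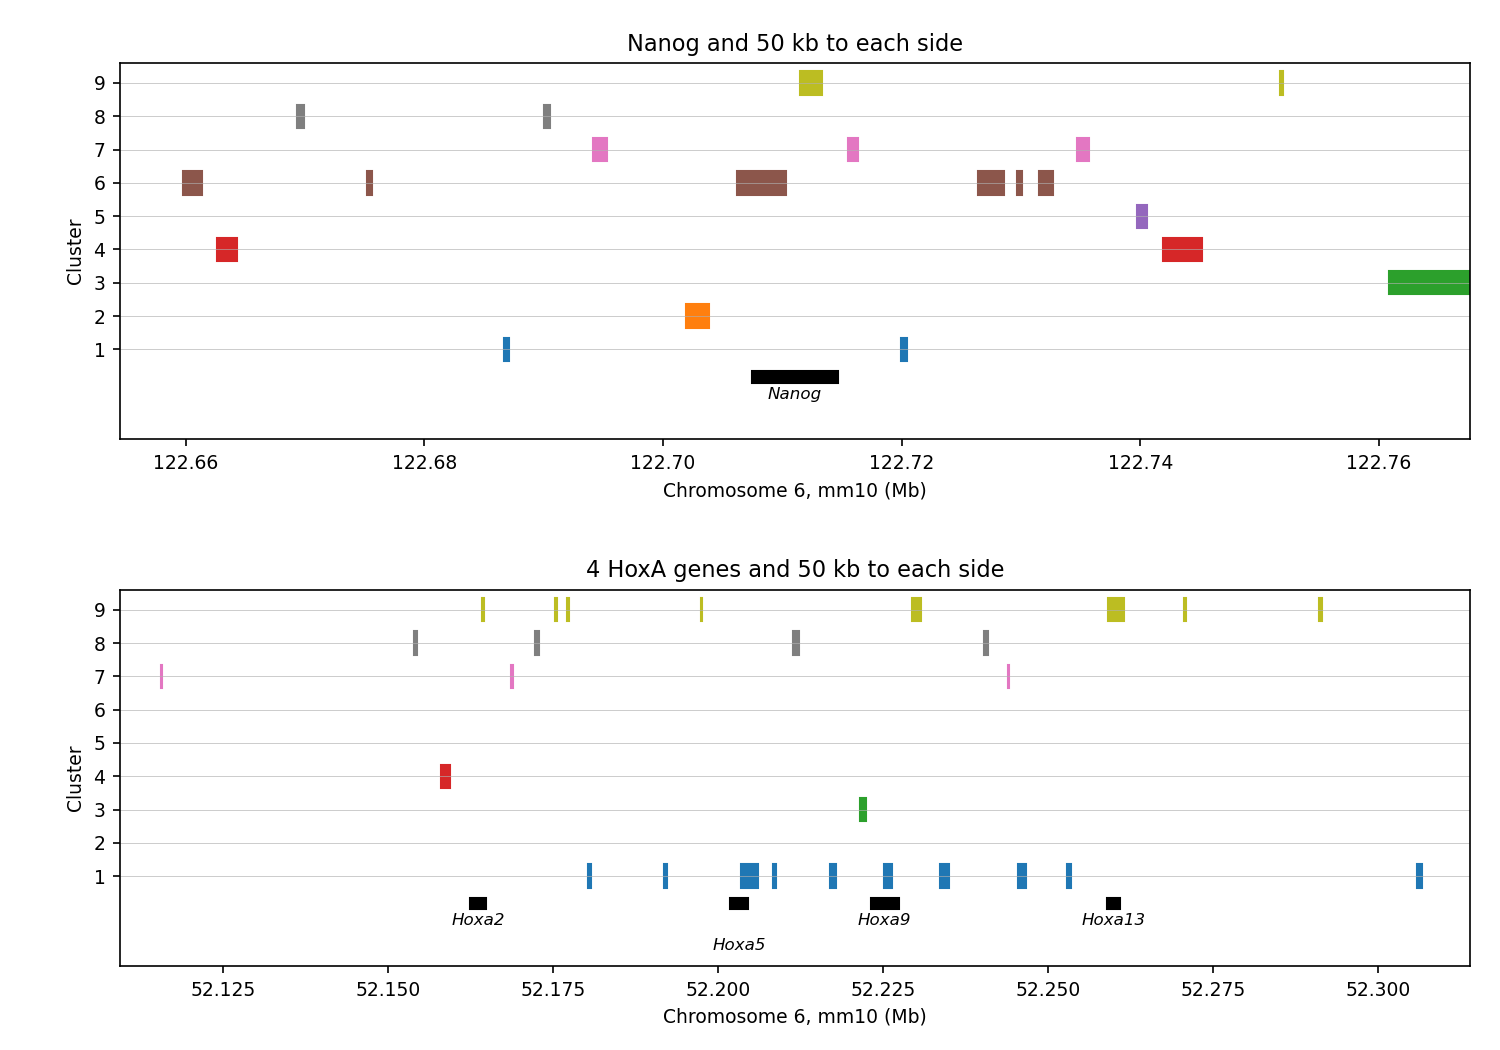
Accessible regions (coloured boxes, a line per cluster) within 50 kb of Nanog and of the HoxA genes Hoxa2, Hoxa5, Hoxa9 and Hoxa13, with these genes as black bars, other genes not drawn, and the mm10 position on chromosome 6 (Mb) as horizontal axis. Around Nanog 6 of 20 regions belong to cluster 6, and around the HoxA genes 10 of 27 belong to cluster 1 and none to cluster 2, 5 or 6.

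Regions of certain clusters sat next to each other. A pair of cluster 5 regions within 10 kb was 1.52 times as frequent as under permuted labels, and pairs of cluster 6 with cluster 2 and with cluster 5 were 1.51 and 1.49 times as frequent. Cluster 6 regions also paired with each other (ratio 1.44), as did those of cluster 1 (1.36) and cluster 8 (1.30), and clusters 1 and 8 paired with each other (1.30). The most numerous cluster, cluster 9, lay less often next to some of them. It was next to cluster 5 at a ratio of 0.642, to cluster 2 at 0.740 and to cluster 6 at 0.747. In all, 19.1% of 32823 pairs shared a cluster, against 17.2% (range 16.6% to 17.9%) in 1000 permutations within chromosomes (one-sided permutation p = 0.001, the smallest they can give). Each of the ratios named here passed (two-sided permutation adjusted p = 0.00473), as did 24 of 45 kinds of pair. Because neighbours resemble each other, p-values that treat regions as independent are too small.

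**Figure D4:**
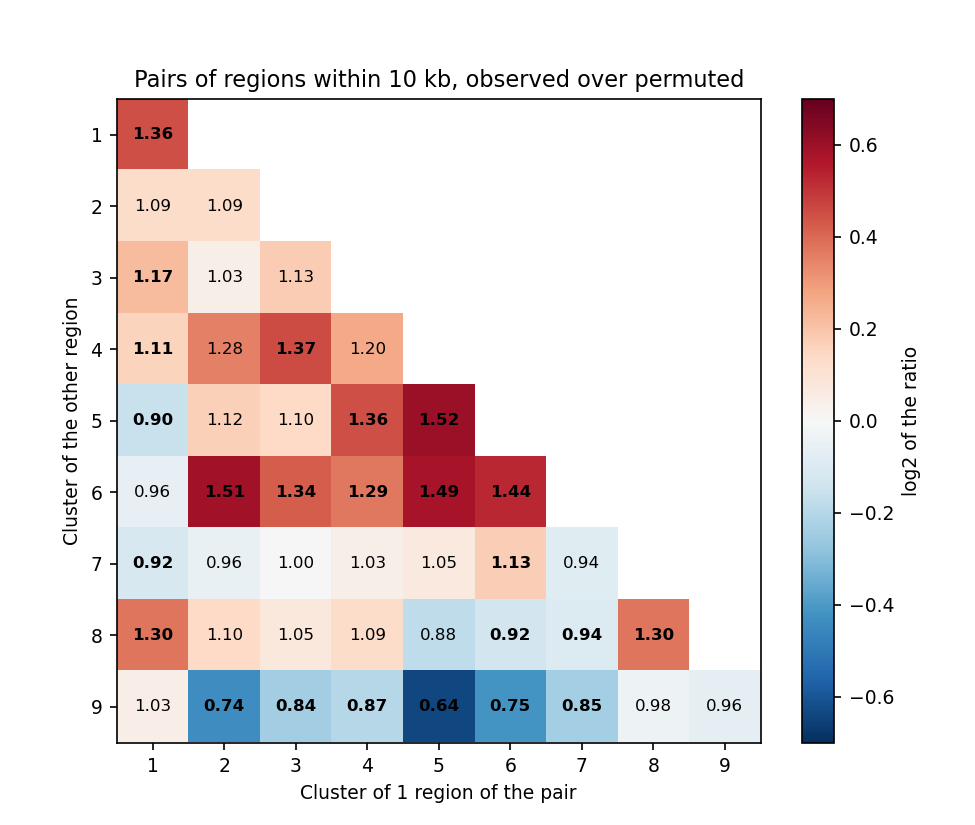
Number of pairs of adjacent regions within 10 kb for each combination of clusters, divided by the mean of 1000 permutations of the cluster labels within chromosomes. Bold values passed the adjusted threshold, and pairs of cluster 5 with itself reach 1.52 and pairs of clusters 5 and 9 fall to 0.642.

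Chromosome X carried a different mix of clusters from the autosomes. Cluster 5 made up 11.6% of its 1371 regions, against 4.93% of all other regions, and at the gene ends of chromosome X the share was 17.5% (67 of 383 regions), against 4.06%. Clusters 6 and 7 were also more frequent there, whereas the gene-end clusters 2, 3 and 4 were less frequent. Chromosome X was sparsely covered, with 8.03 regions per Mb, against 20.6 to 42.6 per Mb over the autosomes. The odds ratio of lying on chromosome X was 2.53 (95% CI 2.14 to 2.99) for cluster 5 and 1.48 for cluster 6, above 1 for cluster 7, and 0.828 for cluster 1, 0.375 for cluster 2, 0.291 for cluster 3, 0.448 for cluster 4 and 0.791 for cluster 9. All 8 passed Fisher's exact test, two-sided, adjusted over all chromosomes and clusters, and cluster 8 did not (0.832, exact adjusted p = 0.153). Among distal regions alone cluster 2 no longer passed (0.701, exact adjusted p = 0.599) and cluster 8 did (0.601, exact adjusted p = 0.00623).

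Across the 19 autosomes the mix followed gene density. Chromosomes with more protein-coding genes per Mb had larger shares of cluster 1 (Pearson r = 0.71, permutation adjusted p = 0.00423, Spearman rho = 0.71, permutation adjusted p = 0.00540) and cluster 8 (r = 0.64, permutation adjusted p = 0.00482, rho = 0.64, permutation adjusted p = 0.00828). Their shares were smaller for cluster 7 (r = -0.76, permutation adjusted p = 0.00036, rho = -0.75, permutation adjusted p = 0.00540), cluster 6 (r = -0.65, permutation adjusted p = 0.00482, rho = -0.64, permutation adjusted p = 0.00828) and cluster 5 (r = -0.62, permutation adjusted p = 0.00482, rho = -0.63, permutation adjusted p = 0.00828). Without chromosomes 7 and 11, the farthest from the median density, these 5 values of r were 0.69, 0.67, -0.70, -0.65 and -0.61. The relations of clusters 3 and 4 (r = 0.56 and 0.58, permutation adjusted p = 0.0199 and 0.0150) rested on those chromosomes, since r fell to 0.29 and 0.26 without them, and by rank cluster 3 passed and cluster 4 did not (rho = 0.53 and 0.48, permutation adjusted p = 0.0336 and 0.0537). Clusters 2 and 9 showed none that passed (r = 0.32 and 0.23). All 9 relations were computed, and they were chosen after the cluster tables had been seen. The 9 shares of a chromosome add up to a fixed whole, so the relations are not independent. The share of gene-end regions also differed, from 15.6% on chromosome 18, the autosome with fewest genes per Mb, to 23.4% on chromosome 7, with most. No relation among distal regions alone is given, so the part that position plays is not known.

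**Figure D5:**
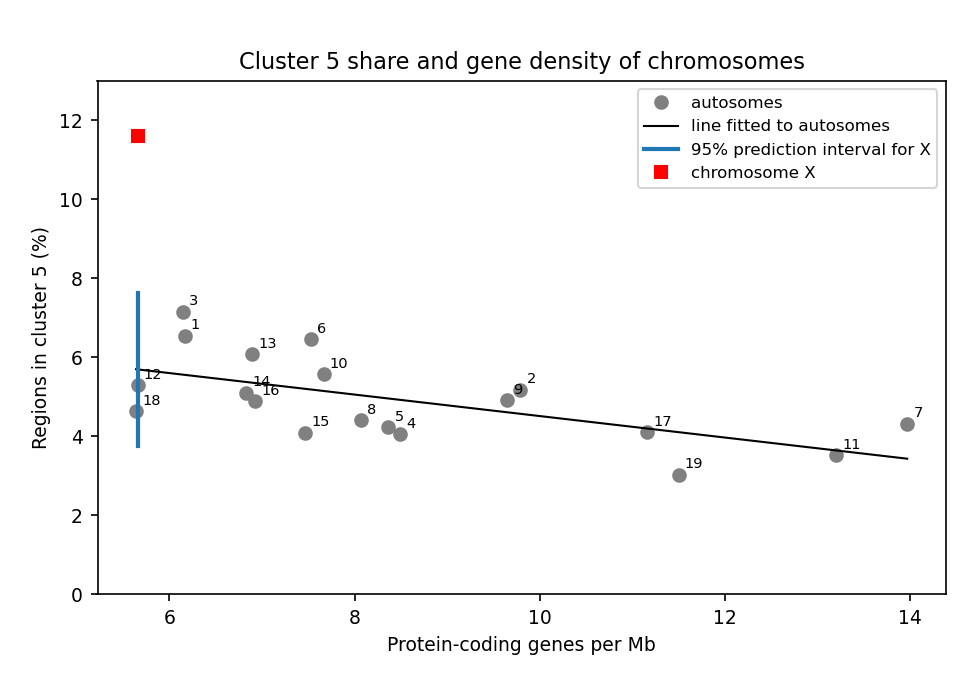
Share of regions in cluster 5 (%) against protein-coding genes per Mb for 19 autosomes (grey points, numbered) and chromosome X (red square), with the line fitted to the autosomes and the 95% prediction interval at the gene density of chromosome X (blue). Chromosome X lies at 11.6%, above the interval of 3.75% to 7.63%.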

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

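Among the tests in this part, the comparison with gene density and both tests on fibroblast genes were chosen only after the result was seen.

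Regions on chromosome Y and on an unplaced scaffold drew attention because no comparison looked at them on their own. They are part of the totals over all regions. Chromosome Y held 11 regions, 5 of cluster 9, 2 of cluster 1 and 1 each of clusters 5, 6, 7 and 8. The unplaced scaffold JH584304 held 12 regions over 68.1 kb, with a mean width of 3773 bp. Of 21951 windows of that span on placed chromosomes that held a region, 0.797% (175) held as many, up to 16, and a window held 2 at the median. So many wide regions on so short a piece may come from repeats collapsed in the assembly, a possible explanation that no read depth was at hand to test further. The labels give no sex for the cells, although the plan took R1 cells to carry a single set of sex chromosomes. No biological explanation was tested for either.

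Cluster 5 regions lay on chromosome X more often than other regions, with an odds ratio of 2.53 (95% CI 2.14 to 2.99). A pile-up at a few loci is argued against, since without the 3 bins of 5 Mb with most cluster 5 regions the odds ratio was 2.20 (1.81 to 2.67). A shortage of gene-end regions shifting the mix is argued against as well, since gene ends made up 27.9% of chromosome X regions, more than the 15.6% to 23.4% of the autosomes, and among distal regions alone the odds ratio was 1.90 (1.53 to 2.36). Low gene density as the whole cause is argued against by a share of 11.6% on chromosome X, above the interval of 3.75% to 7.63% that the autosomes give for 5.66 genes per Mb. A lower copy number of chromosome X could act on all of its regions, and the plan took R1 cells to carry a single set of sex chromosomes. The odds ratio at gene ends was 5.01 (3.79 to 6.61), well above the 1.90 (1.53 to 2.36) of distal regions. A value above 1 was nearly given, since the overall odds ratio exceeded the distal one, so it does not bear on this explanation. Whether copy number would act equally on both kinds of region was not tested. The explanation stays open, because neither signal nor copy number was measured here.

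Fibroblast genes had cluster 9 regions at gene ends in 7 of 20 cases (35%), against 10.3% of other genes, which did not pass adjustment (Fisher's exact adjusted p = 0.0847, and 0.0398 with the nearest region only and 0.0450 with any overlap). Chromatin of remaining feeder fibroblasts might contribute, although the labels state that feeder cells were removed by replating, and the collagen genes Col1a2 and Col1a1 were in clusters 9 and 1. The fibroblast list shares Pdgfra and Sparc with the primitive endoderm list. Against the pooled primitive endoderm, trophoblast, haematopoietic, liver, neuronal and muscle lists (9 of 48, 18.75%), the odds ratio was 2.33 (0.724 to 7.52, exact p = 0.210). These pooled lists had an odds ratio of 2.01 (0.971 to 4.15) against other genes, so cluster 9 at genes of other lineages in general is a second possibility. The list of developmental transcription factors, not pooled here though it shares some genes with the pool, had cluster 9 regions at 13 of 51 genes. Its odds ratio was 2.97 (Fisher's exact adjusted p = 0.0847). With 20 and 48 genes the explanations cannot be told apart.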

How the results depend on the processing

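Regions over 1 kb from every gene end, 1 gene per 500 kb, genes held by a single list, any overlap for gene lists, permutation within position class and genes longer than 5 kb were alternatives chosen after seeing the data. Of the values that answer a comparison, 109 kept their direction and side of the threshold (for values without a test, their size), 5 moved and 3 were weaker. Of values for single lists, chromosomes or pairs of clusters, 227 stayed, 17 were stronger, 24 weaker and 4 reversed.

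The odds ratios for gene ends kept their direction and call in all 9 clusters with a window of 2.5 kb, any overlap, all annotated genes, autosomes only, 1 region per 50 kb and genes longer than 5 kb. With a window of 500 bp, those of cluster 1 (1.02) and cluster 5 (0.979) did not pass, and with regions of middle width that of cluster 5 (0.992) did not. The cause was not tested.

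At gene ends the number of list calls was 1 with a window of 500 bp, 6 with 2.5 kb and 6 with any overlap, against 2. Around genes it was 2 at 1 to 20 kb and 1 for regions over 1 kb from every gene end, against 6. Fewer regions enter with both of these distal alternatives, and otherwise the cause was not tested. Reversed were the pairs of clusters 1 and 5 within 2 kb (ratio 1.16), of clusters 6 and 8 within 2 kb (1.06) and of cluster 9 with itself within 50 kb (1.11). The share of developmental transcription factors with an accessible gene end at 500 bp, counted among the 4, showed no difference (odds ratio 1.00) rather than a turned direction. The cause was not tested. The share of neighbours in the same cluster exceeded permutation by ratios of 1.10 within 2 kb, 1.12 within 50 kb and 1.11 within position class.

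No paired analysis was possible because the table has no columns per library, although the labels share replicate numbers. For the same reason the replicate term, leaving out each replicate, other normalisations and low-value filters were not run. The alternatives for GC content, motifs and repeats were not run without a genome sequence, and the upper part by score was not run without a score. Selecting regions more than 1 kb from the next removed none. Depth is not known and its limits could not be assessed.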

Other observations

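All gene families, RNA classes and tests in this part were chosen only after the cluster tables were seen. Clustered histone genes, which encode the histones made during DNA replication, were examined because the genes with most cluster 3 regions nearby belonged to them, so no test is given for this family. Of the 53 of 66 genes with a gene-end region, 22 had a cluster 3 region, through 13 distinct regions, since neighbouring genes share regions, and only 2 had a cluster 1 region. Zinc finger genes named Zfp had cluster 5 regions in 27 of 312 cases (odds ratio 1.88, exact adjusted p = 0.0361). They had cluster 1 regions less often than other genes, in 46 of 312 cases (odds ratio 0.621, exact adjusted p = 0.0289). Keratin genes had cluster 9 regions in 7 of 12 cases (exact adjusted p = 0.00113). Protocadherin genes had cluster 6 regions in 22 of 30 cases, through only 3 distinct regions. Olfactory receptor genes had a gene-end region in 16 of 1110 cases (1.44%) and vomeronasal receptor genes in 4 of 355 (1.13%).

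Genes for small RNAs outside protein-coding gene ends also differed. Shares were taken over all regions of each cluster, although regions at protein-coding gene ends could not count. This lowers the shares and odds ratios of clusters 2, 3, 4 and 8, which lie there most often. Regions at transfer RNA genes were more often of cluster 4 (odds ratio 4.30, 95% CI 2.61 to 7.08, exact adjusted p = 1.55e-05), cluster 3 (exact adjusted p = 0.00300), cluster 5 (2.17, exact adjusted p = 0.0432) and cluster 8 (2.07, exact adjusted p = 0.0235), and less often of cluster 7 (0.199) and cluster 9 (0.153). Regions at small nuclear RNA genes were more often of cluster 3 (7.66, 4.39 to 13.4, exact adjusted p = 1.10e-07) and cluster 2 (3.92). By this measure, microRNA genes were linked to cluster 1 (1.73, exact adjusted p = 0.0328), as were long non-coding RNA genes (1.20, exact adjusted p = 0.00152). Among distal regions cluster 1 did not rank highest for either. Long non-coding RNA genes took 601 of 10304 distal regions in cluster 1. They took 52 of 566, 90 of 905, 87 of 903 and 290 of 3410 in clusters 2, 3, 4 and 8, and lower shares in clusters 5, 6, 7 and 9. MicroRNA genes took 37 of 10304 in cluster 1 and 7 of 903 in cluster 4. No cluster passed for small nucleolar RNA genes. A region lay at 236 of 408 transfer RNA genes (57.8%) and at 86 of 1004 small nuclear RNA genes.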
